A study of Homo sapiens with 6 samples.

How the data were processed

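Messenger RNA of 2 human triple-negative breast cancer cell lines was profiled by RNA sequencing in 6 libraries. Per the labels, the lines were HCC1806RR and SUM1315, the cells carried an shRNA against ΔNp63 or a vector, total RNA was made into stranded mRNA libraries, and these were sequenced on a NextSeq instrument. What the letters RR stand for is not given in the sources used here. The labels place 1 library in the HCC1806RR shΔNp63 group, 2 in the HCC1806RR vector group, 2 in the SUM1315 shΔNp63 group and 1 in the SUM1315 vector group. The series describes the libraries as biological replicates without saying what separates them, so the p-values measure the spread between these libraries, which may in part be technical. In the comparison over both lines, the spread also takes in any difference of the effect between the lines.

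The deposited table holds TPM values (transcript abundance scaled to a fixed total) for 56638 gene symbols, and each library's TPM values sum to 1000000. The submitters' processing notes name the GRCh37 genome build, TopHat2 2.1.1, Bowtie2 2.2.6 and featureCounts 1.5.0, without their roles or order. How the authors' TPM values were scaled further, and which gene annotation and strand setting were used, is not given in the sources used here. No read totals were used, since TPM keeps no depth. An approximate depth was recovered from short single-exon genes. TPM multiplied by the gene length in GENCODE release 29 fell on whole multiples of a step in each library, within a tolerance of 0.02, for 77.4% to 81.6% of such genes. The lengths belong to a later build than the one the notes name, so the depths of 22.2 M to 27.8 M reads (M, 1000000) and the read numbers given for single genes are estimates. No coordinates are given for the same reason. Of the 56638 symbols, 34360 matched that annotation, and 81.5% of the genes tested did.

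Values were analysed as log2(TPM + 1), so a log2 difference understates the change of genes near 0. Genes with a mean TPM of at least 1 over the 6 libraries were tested, which left 16872. Linear models were fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. shΔNp63 was compared with vector over both lines in an additive model with the cell line as a covariate. Effects within each line, their difference (the SUM1315 effect minus the HCC1806RR effect) and the difference between the vector groups came from a model with 1 mean per group, in which a lone library is assumed to vary like the groups of 2.

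Before the data were examined, 29 gene lists were fixed: p63 epithelial targets, basal keratins and markers, epidermal differentiation, luminal epithelial, mesenchymal, chemokines, cytokines, NF-κB targets, interferon response, MHC class I, mitosis, DNA replication, p53 targets, Wnt, Notch, TGF-β and YAP targets, proteases, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, oxidative stress, immediate early genes, immune checkpoints, leukocyte, fibroblast and endothelial markers, ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. The chemokine list includes the 2 chemokines of the series title. Each list with at least 5 tested genes was tested with limma's camera at a preset correlation of 0.01, adjusted over 28 lists; 4 of the endothelial markers were tested, so that list was not. camera with a correlation estimated per list and fry were the alternatives; fry tests a list against no change, not against other genes. Named genes followed a rule fixed at the same time: TP63, CXCL2 and CCL22 always; the largest changes past the threshold in each comparison, or the 5 smallest p-values where none passed; and up to 4 members of each list past the threshold, or up to 2 where none passed. Clone-style identifiers, pseudogenes and genes on the Y chromosome were passed over. Some genes that the rule names are not reported here.

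The fits were tested on simulated data with the spread of these libraries and 16872 genes, of which 50 changed at each size. In the additive fit 6% of log2 changes of 1, 90% of changes of 2, 98% of changes of 3 and 100% of changes of 4 were recovered, with 11 false calls. In the HCC1806RR contrast 24% of changes of 2 and 94% of changes of 3 were recovered, and in the SUM1315 contrast 22% and 90%. Changed genes were drawn from those with a mean log2 value above 3 and changed equally in both lines, with independent noise. The recovered shares therefore do not cover weakly expressed genes or effects that differ between the lines. They also rest on many strong changes planted in 1 fit, which eases the adjustment over genes. In the data, TP63 in HCC1806RR did not pass, although its log2 difference exceeded 3 in size. A count of 0 genes past the threshold thus does not exclude changes of the sizes simulated. Alternatives were 2 other pseudocounts (0.1 and 0.5), no filter, a mean TPM of at least 5, median-of-ratios and quantile scaling, no variance trend, a fold threshold, blocks by replicate number, an average of the within-line contrasts and leaving out each library. Fits on replicate 1 libraries, on protein-coding genes, on genes of at least 200 nt and on 1 cell line at a time, and list tests of the difference over 9673 genes with a mean of at least 5 TPM in each line (23 lists with at least 5 members), were added after the data were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared tables and figures.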

Results

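RNA sequencing covered 2 triple-negative breast cancer cell lines with an shRNA against ΔNp63, the isoform of the transcription factor p63 that lacks the N-terminal activation domain, or with a vector. The 6 libraries comprised 3 labelled shΔNp63 (1 of HCC1806RR, 2 of SUM1315) and 3 labelled vector (2 of HCC1806RR, 1 of SUM1315). Estimated depths ran from 22.2 M to 27.8 M reads (M, 1000000). Between 15194 and 16614 genes reached 1 TPM. Mitochondrially encoded genes took 27.1% of the TPM in HCC1806RR shΔNp63 replicate 1, 28.1% and 18.97% in its vector replicates 1 and 2, 28.9% and 14.7% in SUM1315 shΔNp63 replicates 1 and 2, and 34.8% in the SUM1315 vector library. Within each line the replicate 2 library stood apart: across tested genes SUM1315 shΔNp63 replicate 1 correlated with the vector library at r = 0.986 and with shΔNp63 replicate 2 at r = 0.945, and HCC1806RR shΔNp63 replicate 1 correlated with vector replicate 1 at r = 0.969 and with vector replicate 2 at r = 0.928. The 2 HCC1806RR vector libraries correlated with each other at r = 0.95. On the log2 scale, vector replicate 2 minus replicate 1 had an SD of 0.664 in HCC1806RR. For shΔNp63 replicate 1 minus vector replicate 1 it was 0.522. In SUM1315 the SD was 0.756 for shΔNp63 replicate 2 minus replicate 1 and 0.376 for shΔNp63 replicate 1 minus vector. Replicates thus differed more than the replicate 1 pairs of shΔNp63 and vector. These correlations and SDs are across genes, which are not independent replicates.

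The target gene was examined first. The TP63 value sums all isoforms, so it does not separate ΔNp63 from the longer TA forms. In HCC1806RR, TP63 stood at 15.7 TPM in the shΔNp63 library and at 151 and 170 TPM in the vector libraries. In SUM1315 it stood at 11.7 TPM in shΔNp63 replicate 1 and 27.4 TPM in the vector library, but at 43.9 TPM in the library labelled shΔNp63 replicate 2, which is above the vector and against its label. The TP63 log2 difference was -3.27 in HCC1806RR (SE 0.724, limma adjusted p = 0.511), -0.25 in SUM1315 (adjusted p = 1) and -1.76 over both lines (SE 0.735, adjusted p = 1). Without SUM1315 shΔNp63 replicate 2 it was -1.16 in SUM1315 and -2.37 over both lines. Without SUM1315 shΔNp63 replicate 1 it was 0.66 in SUM1315. The median of all genes was 0.357 in that pair of libraries, so all genes share part of this rise. Among replicate 1 libraries alone the TP63 log2 difference was -2.17. CXCL2, a neutrophil and myeloid chemoattractant, stood at 4.64 TPM in the HCC1806RR shΔNp63 library against 12.3 and 12.2 TPM in vector. In SUM1315 it stood at 28.4% of the vector level in shΔNp63 replicate 1, with 68.7 TPM in the library labelled shΔNp63 replicate 2 and 36.4 TPM in vector. Its log2 difference over both lines was -0.82 (SE 0.664, limma adjusted p = 1), and ranged from -1.442 to -0.321 with 1 library left out. CCL22, a ligand of the chemokine receptor CCR4, was below the expression filter and was not tested: it stood at 0.528 TPM against 3.65 and 1.35 TPM in HCC1806RR and at 0.0503 TPM or less in all 3 SUM1315 libraries.

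**Figure D1:**
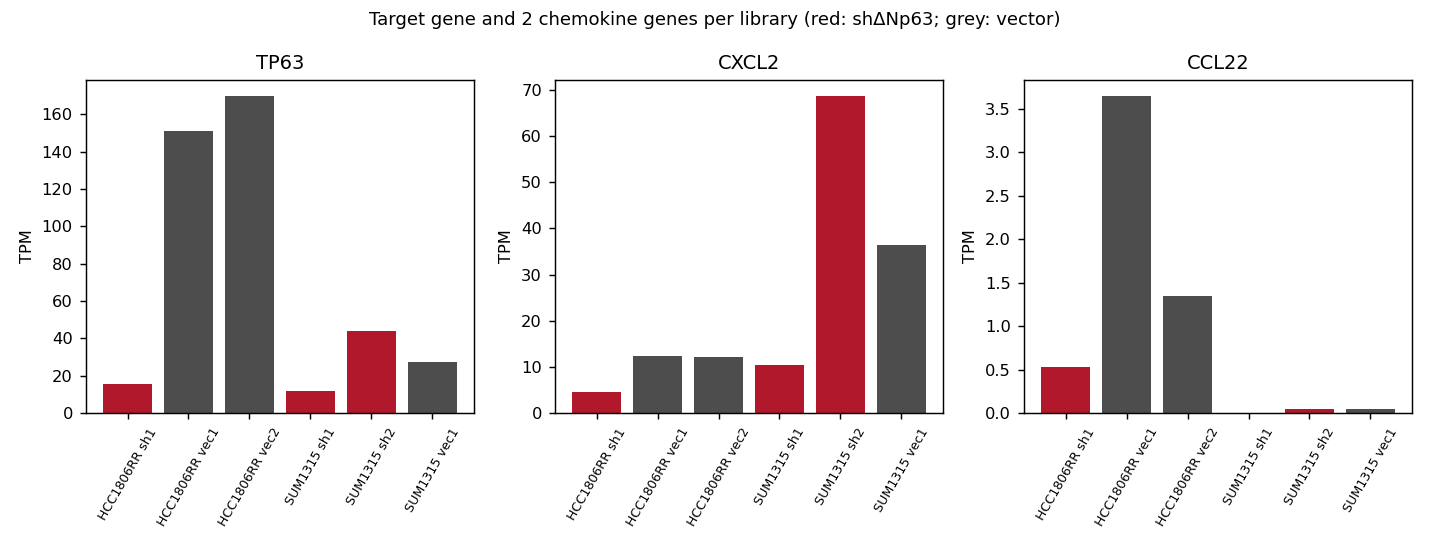
TPM of TP63, CXCL2 and CCL22 in each of the 6 libraries, with 1 bar per library and an axis from 0 for each gene. TP63 and CXCL2 in the SUM1315 library labelled shΔNp63 replicate 2 stand above the SUM1315 vector library, at 43.9 and 68.7 TPM.

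The main comparison asked which genes differed between shΔNp63 and vector over both lines. Of the genes not passed over, the 5 smallest limma p-values belonged to MIR302A, SAA2, MIR99B, SNORD119 and SAA1, none past the threshold. S100A9 was named as a member of a gene list and did not pass either. SAA1, an acute-phase apolipoprotein, stood at 2.7 TPM in HCC1806RR shΔNp63 against 33.4 and 36.6 TPM in vector, and at 21.7 and 2.7 TPM in SUM1315 shΔNp63 against 68.8 TPM, a log2 difference of -3.11 (limma adjusted p = 1). Its paralog SAA2, which can share reads with it, had a log2 difference of -2.26. S100A9, a calcium-binding protein of inflamed epithelium and myeloid cells, stood at 5.81 TPM against 115 and 286 TPM in HCC1806RR and at 13.1 and 4.85 TPM against 29.5 TPM in SUM1315 (log2 difference -3.25, adjusted p = 1). The receptor tyrosine kinase AXL had a log2 difference of 1.72 and fibronectin (FN1) of 1.13, both higher in each shΔNp63 library than in each vector library of its line. MIR302A, MIR99B and SNORD119 had log2 differences of 1.93, 1.74 and 2.48, and both microRNA genes rested on at most 2 estimated reads per library.

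By limma, 0 of 16872 genes passed the threshold over both lines, and 298 had an unadjusted p under 0.05, with 844 expected by chance. Of these, 180 were higher and 118 lower in shΔNp63. The residual of this fit also holds any difference of the effect between the lines, which can raise the p-values. The model with 1 mean per group lacks this term, and its shΔNp63 counts given below also lay under 844. This term alone therefore does not account for the shortfall. Among replicate 1 libraries alone 0 genes passed, with 873 at an unadjusted p under 0.05; the replicate 2 libraries number 1 per line and give no value. Directions drawn from SUM1315 include the library whose TP63 level goes against its label, except where it is said to be left out.

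Gene lists were compared with all other genes. With the preset correlation 15 of 28 lists passed over both lines, 6 higher and 9 lower, and 0 passed with an estimated correlation. By fry, which asks whether a list changed at all and not whether it differs from other genes, 0 passed. No member of any list passed over all genes tested or when adjusted over the list alone. The mesenchymal list had 23 of 26 tested members above 0 and a median log2 difference of 0.54 (camera adjusted p = 1.56e-07; adjusted p = 0.759 with an estimated correlation). The p63 epithelial targets had 22 of 29 members below 0 and a median of -0.47 (adjusted p = 3.15e-06; 0.759 as the adjusted p with an estimated correlation), among them the Notch ligand JAG2 (log2 difference -1.37) and the desmosomal cadherin DSC3 (-1.26). DSC3 was at 0.32 TPM or less in SUM1315, so its value only restates HCC1806RR, and without HCC1806RR shΔNp63 replicate 1 JAG2 was at -0.64 and DSC3 at -0.19. The Notch list had a median of -0.75 (adjusted p = 4.37e-06) and the epidermal differentiation list of -0.21 (adjusted p = 9.61e-05), with adjusted p = 0.759 and adjusted p = 0.519 when the correlation was estimated. The epidermal list includes S100A9 and the elastase inhibitor PI3 (-2.28). Basal keratins and markers had a median of -0.14, with KRT6A at -1.23 and KRT14 at -0.72; both were at 0.5 TPM or less in SUM1315, so they describe HCC1806RR, and KRT6A shares near-identical sequence with KRT6B and KRT6C and is uncertain. Chemokines had a median of -0.24 (-0.492 to 0.011 with 1 library left out), with CXCL16 at -0.60 and CXCL1 at -0.89. CXCL1 was at 0.341 TPM or less in SUM1315, and without HCC1806RR shΔNp63 replicate 1 its value was 0.14. The unfolded protein response list had a median of 0.47, with EDEM1 at 0.63 and SEL1L at 0.54. Its median was 0.082 in HCC1806RR and 0.6 in SUM1315. Mitosis (0.42), TGF-β and YAP targets (0.25), proteases and inhibitors (0.18) and histones (0.45) lay higher, with the metalloproteinase inhibitor TIMP2 at 1.06. Mitochondrially encoded genes (-0.31), ribosomal proteins (-0.09), DNA replication (-0.15) and interferon response (-0.10) lay lower. With an estimated correlation the adjusted p was 0.759 for the basal, chemokine, unfolded protein response, mitosis, TGF-β, protease, histone and mitochondrial lists and 0.791 for the ribosomal, DNA replication and interferon lists.

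The other 13 lists did not pass over both lines. Their median log2 differences were 0.15 for luminal genes, 0.12 for cytokines, 0.02 for NF-κB targets, -0.05 for MHC class I, 0.20 for p53 targets, 0.11 for Wnt, 0.14 for hypoxia and glycolysis, 0.14 for cholesterol synthesis, 0.21 for oxidative stress, 0.05 for immediate early genes, 0.14 for immune checkpoints, -0.19 for leukocyte markers and 0.29 for fibroblast markers. For cytokines, NF-κB targets and Wnt the median lay above 0 while the mean and the test pointed down. The median of all genes was 0.087, so small positive medians match the shift of all genes. Of the 15 calls, 1 (epidermal differentiation) held whichever library was left out. Without HCC1806RR shΔNp63 replicate 1, which leaves the SUM1315 comparison, 8 lists passed, the p63 median was 0.13 and the Notch median 0.03 (adjusted p = 0.659 for both). Without the SUM1315 vector library, which leaves HCC1806RR, the mesenchymal median was 0.007 (adjusted p = 0.0946), so that call rested on SUM1315. Without HCC1806RR vector replicate 2 the mitosis median was 0.12 (adjusted p = 0.91), and without SUM1315 shΔNp63 replicate 2 the DNA replication median was 0.13.

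Within HCC1806RR the question was what differed where TP63 was lowest relative to vector. Several of the genes with the smallest p-values had far lower values in the shΔNp63 library than in both vector libraries, though none passed the threshold. OLFM4, a secreted glycoprotein, stood at 1.96 TPM against 72 and 71.4 TPM (log2 difference -4.62, SE 0.476). PIGR, the polymeric immunoglobulin receptor, stood at 1.41 TPM against 45.8 and 63 TPM (-4.50). The atypical chemokine receptor ACKR3 stood at 7.13 TPM against 141 and 299 TPM (-4.66), and podoplanin (PDPN) at 0.66 TPM against 28.2 and 67.7 TPM (-4.75). Keratin 5 (KRT5) stood at 99.5 TPM against 639 and 628 TPM (-2.66). Higher in the shΔNp63 library were ANKRD1, a YAP target, at 155 TPM against 17.5 and 5.66 TPM (3.81), and the phosphatase DUSP4 at 18.4 TPM against 1.8 and 1.25 TPM (2.95). MIR544B (2.93) rested on at most 4 estimated reads. By limma 0 of 16872 genes passed (smallest adjusted p = 0.347). An unadjusted p under 0.05 was found for 664, 248 higher and 416 lower, fewer than the 844 expected by chance. When protein-coding genes alone were tested, 8 genes passed, all lower (smallest adjusted p = 0.0127), among them OLFM4, PIGR, PDPN, ACKR3 and S100A9. At a mean TPM of at least 5, an alternative fixed in advance, OLFM4, PIGR, PDPN and ACKR3 passed (adjusted p = 0.0272 to 0.046). The protein-coding fit was chosen after the data were seen, and the others so chosen gave 0 genes: genes of at least 200 nt (smallest adjusted p = 0.0677) and libraries of this line alone (0.557). The shΔNp63 group is 1 library, assumed to vary like the other groups.

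**Figure D2:**
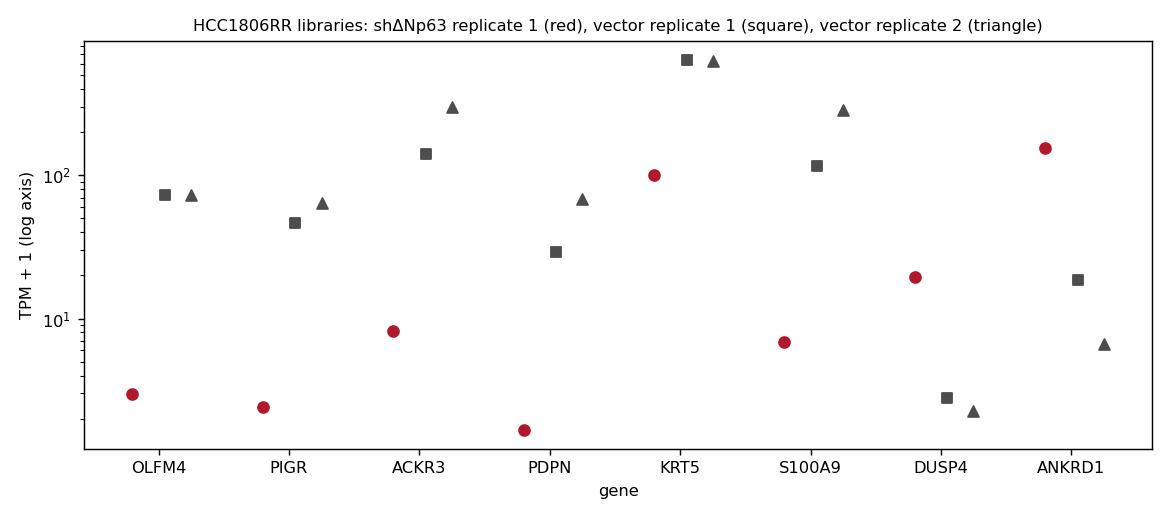
TPM + 1 on a log axis of 8 genes in the 3 HCC1806RR libraries, with 1 point per library. OLFM4 stands at 1.96 TPM in the shΔNp63 library and at 72 and 71.4 TPM in the vector libraries, while ANKRD1 stands at 155 TPM against 17.5 and 5.66 TPM.

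Of 28 lists, 11 passed in HCC1806RR with the preset correlation and 0 with an estimated one, where each of the 11 except DNA replication had adjusted p = 0.729. The p63 epithelial targets had 25 of 29 members below 0 and a median of -0.83 (camera adjusted p = 8.38e-10). Adjusted over the list alone 3 were lower; FAT2 had a log2 difference of -2.76 and PKP1 of -2.76. The Notch list had 16 of 17 members below 0 and a median of -1.54 (adjusted p = 8.48e-10), with HES2 at -2.73 and the ligand DLL1 at -3.18, and 2 lower adjusted over the list alone. Basal keratins and markers had a median of -0.56, with KRT5 and VTCN1 (-2.96) and 3 lower adjusted over the list alone. Epidermal differentiation had a median of -0.44, with S100A9 at -4.75 and KRT13 at -2.37 and 2 lower adjusted over the list alone. Interferon response genes had 31 of 35 members below 0 and a median of -0.57, with IFI6 at -1.95 and CMPK2 at -1.28. NF-κB targets (-0.52), MHC class I (-0.53), Wnt (-0.34, with WNT4 at -3.82 and TCF7L1 at -3.56) and ribosomal proteins (-0.55) also lay lower. Mitosis (0.62) and DNA replication (0.19, adjusted p = 0.83 with an estimated correlation) lay higher, but against vector replicate 1 alone, the mitosis median was -0.06 and the DNA replication median -0.20. Without vector replicate 2 the medians were also nearer 0 for Notch (-0.88, still past the threshold), ribosomal proteins (-0.13, adjusted p = 0.221), MHC class I (-0.24, adjusted p = 0.3), basal markers (-0.32), epidermal differentiation (-0.29, adjusted p = 0.0789) and Wnt (-0.28, adjusted p = 0.211). Of the 11 calls, 4 held whichever of 5 libraries was left out: p63 targets, basal markers, interferon response and Notch. The lone shΔNp63 library, on which every call rests, could not be left out. Leaving out a SUM1315 library does not change these medians, so only the vector libraries put them to a test. Vector replicate 2, the library that stands apart, is low in the mitosis and DNA replication lists and in mitochondrial TPM. Chemokines had a median of -0.49 (adjusted p = 0.0584), with CXCL1 at -1.92. Adjusted over the list alone, 3 immediate early genes were higher, among them DUSP4 and FOSL1 (2.27), and 2 immune checkpoint genes were lower, IDO1 (-3.13) and VTCN1. Of the leukocyte markers, CD74 stood at 43.3 TPM against 126 and 503 TPM. The fibroblast markers went both ways (4 above 0, 5 below, median -0.02, adjusted p = 0.075), with C1R at 1.37 TPM against 9.38 and 17.1 TPM.

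Within SUM1315 the same comparison set 2 shΔNp63 libraries, 1 of them with TP63 above the vector, against 1 vector library. SCG2, a granin of secretory vesicles, stood at 14.4 and 56.6 TPM against 0.44 TPM (log2 difference 4.37, SE 0.78). LCN2, an iron-siderophore-binding protein, stood at 4.34 and 0.86 TPM against 37 TPM (-3.59). Type III collagen (COL3A1) stood at 38.9 and 96.3 TPM against 12.1 TPM (2.25), and the collagen cross-linking enzyme LOX at 5 and 16.9 TPM against 1.82 TPM (1.88). The carbonic anhydrase CA9 stood at 13.7 and 72.3 TPM against 4.22 TPM (2.66). MIR4667, MIR3192 and SNORD73 were also among the 5 smallest p-values, with the microRNA genes at no more than 5 estimated reads. By limma 0 of 16872 genes passed (smallest adjusted p = 0.462). An unadjusted p under 0.05 was found for 224, 138 higher and 86 lower, fewer than the 844 expected by chance.

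Of 28 lists, 8 passed in SUM1315 with the preset correlation and 0 with an estimated one. The mesenchymal list had all 26 members above 0 and a median of 0.96 (camera adjusted p = 6.21e-11; adjusted p = 0.888 with an estimated correlation), and fibroblast markers, which share members with it, had a median of 0.88 (0.888 as the adjusted p with an estimated correlation). The unfolded protein response median was 0.60, with HERPUD1 at 1.56 and DDIT4 at 2.30; DDIT4 stood at 45.6 TPM in shΔNp63 replicate 1 and 329 TPM in the library labelled replicate 2 against 24.2 TPM. Interferon response genes had a median of 0.44, with IFIH1 at 1.35 and IFI44L at 1.09, and histones of 1.07. With 1 library left out IFIH1 ranged from 0.548 to 2.159 and IFI44L from 0.786 to 1.387. Mitochondrially encoded genes had all 13 members below 0 and a median of -0.87, and DNA replication genes a median of -0.47, with CDC6 at -1.13 and CCNE1 at -0.90 (-0.11 and -0.25 without the library labelled shΔNp63 replicate 2). Epidermal differentiation had a median of 0 and a mean of -0.38, with LCN2 lower adjusted over the list alone and PI3 at -2.69. Leaving out 1 library moved PI3 between -3.876 and -1.499. With an estimated correlation the adjusted p was 0.888 for these lists and 0.928 for interferon. The median of all genes was 0.218. The p63 (0.13), Notch (0.03) and mitosis (0.22) lists did not pass, and their medians and means lay above 0 while the test against all other genes pointed down. Without the library labelled shΔNp63 replicate 2, the DNA replication median was 0.07 (adjusted p = 0.931), the interferon median 0.16 (adjusted p = 0.59) and the histone median 0.31 (adjusted p = 0.311). The unfolded protein response (0.17), fibroblast (0.31) and mitochondrial (-0.36) medians also shrank without it, while their calls held.

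**Figure D3:**
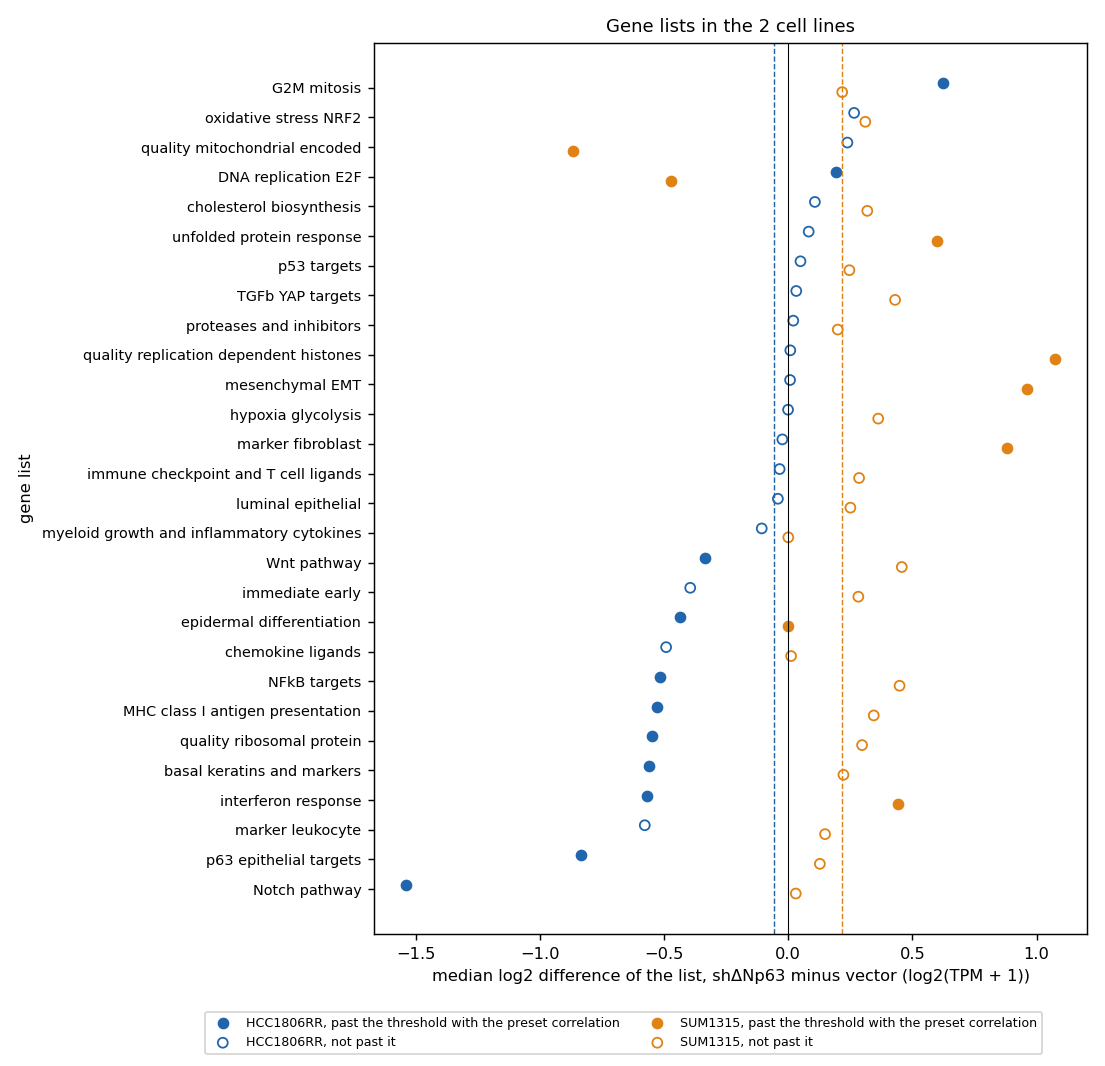
Median log2 difference of each gene list in HCC1806RR and in SUM1315, with filled points for lists past the threshold with the preset correlation and dashed lines at the medians of all genes, -0.056 and 0.218. The Notch list lies at -1.54 in HCC1806RR and 0.03 in SUM1315, and the mesenchymal list at 0.01 and 0.96; no list passes with an estimated correlation.

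Whether the effect differed between the lines was tested directly. OLFM4 (difference 4.56) and ACKR3 (5.63) had 2 of the 5 smallest p-values (adjusted p = 0.748 and 0.803); OLFM4 was at 0.0459 TPM or less in SUM1315, so its difference only restates HCC1806RR, and ACKR3 stood there at 7.49 and 14.6 TPM against 4.89 TPM. MIR3192, MIR544B and SNORD73 had the other 3. By limma 0 of 16872 genes passed (smallest adjusted p = 0.669), and 469 had an unadjusted p under 0.05, fewer than the 844 expected by chance. With the preset correlation 13 lists differed, 10 with a higher value in SUM1315 and 3 lower, and 0 with an estimated correlation. The Notch difference had a median of 1.60 (camera adjusted p = 6.26e-06), with DLL1 at 3.46 and HES2 at 2.58; HES2 was at 0.295 TPM or less in SUM1315, so its difference only restates HCC1806RR. The p63 target difference had a median of 1.14 (adjusted p = 3.84e-06), with FAT2 at 2.86 and PKP1 at 2.76, both near 0 TPM in SUM1315. Over the 18 members with a mean of at least 5 TPM in each line, the p63 median was 0.94 (adjusted p = 0.0048; adjusted p = 0.627 with an estimated correlation). The interferon difference had a median of 1.002 (adjusted p = 1e-07), with IFI44L at 2.68 and IFI6 at 2.31. All 3 had adjusted p = 0.792 with an estimated correlation, and 4 of the 13 calls held whichever of 4 libraries was left out. The HCC1806RR shΔNp63 and SUM1315 vector libraries, each alone in its group, could not be left out. Across the tested genes the effects of the 2 lines correlated at r = -0.059 (Spearman -0.069), and 42.9% had the same sign. The other 8 assignments of the labels within the lines gave r from -0.078 to 0.10. Replicate 1 libraries alone gave r = 0.034 (Spearman 0.082). Of the genes with an unadjusted limma p under 0.05 in both lines, 7 were higher in both, with 2.03 expected for independent lists. Lower in both were 8, with 2.12 expected. The 2 contrasts share each gene's estimate of the spread, so the lists are not independent. An excess over these expected counts can arise without a shared response.

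The vector groups show the starting difference between the lines. SUM1315 expressed a mesenchymal set: vimentin (VIM) stood at 1320 TPM against 0.279 and 0.232 TPM (log2 difference 10.04, limma adjusted p = 0.000803), SPARC at 410 TPM against 0.104 and 0.0682 TPM (8.56), and IGFBP5 (8.22), PKNOX2 (7.34) and NNMT (7.17) were also higher. HCC1806RR expressed an epithelial set: keratin 19 (KRT19) stood at 2420 and 3500 TPM against 0.0569 TPM (-11.43), KRT13 at 1850 and 3630 TPM against 0.0913 TPM (-11.21), and the long non-coding RNA H19 (-10.82) and IGFBP3 (-9.63) were also lower in SUM1315. By limma 3140 of 16872 genes passed, 792 higher and 2348 lower in SUM1315, or 74.8% lower. The median of all genes was -0.339, and the share lower was 63.7% (1257 higher, 2202 lower) with median-of-ratios scaling and 54.7% (1595 higher, 1927 lower) with quantile normalization. Without a filter it was 41.9% (855 higher, 616 lower), with 771 of the 1471 genes at a mean TPM under 1 and 553 above 0 in 1 library alone. The direction of the imbalance thus depends on the filter, and without one many calls are genes seen in 1 library. The SUM1315 group is 1 library. Leaving out either HCC1806RR vector library left 0 genes past the threshold (smallest adjusted p = 0.0525 and 0.0558), and leaving out SUM1315 shΔNp63 replicate 1 or 2, which carry part of the spread, left 418 higher and 759 lower or 482 higher and 867 lower.

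Of 28 lists, 14 differed between the vector groups with the preset correlation, 6 higher and 8 lower in SUM1315, 5 by fry and 0 with an estimated correlation. Of the 14 calls, 8 held whichever of 5 libraries was left out. The SUM1315 vector library, alone in its group, could not be left out. The basal call was lost each time, and the Notch, fibroblast, epidermal, cholesterol and ribosomal calls at least once. The ribosomal median went down to 0.06. Luminal genes had all 21 members below 0 and a median of -4.22 (camera adjusted p = 1.8e-11), among them EPCAM (-8.60), CDH1 (-7.53) and AGR2 (-6.96). The mesenchymal list had a median of 2.90 (adjusted p = 5.21e-15), with FN1 at 5.32 and MMP2 at 5.38. The p63 epithelial targets had a median of -3.31 (adjusted p = 6.82e-09), with GPX2 at -7.86 and TRIM29 at -7.60. Interferon response genes had a median of -2.49, with OAS1 at -5.54 and SAMD9L at -4.60. Basal markers fell on both sides, with KRT5 at -9.18, CDH3 at -6.94 and KRT81 at 5.54 and a median of -2.46. Hypoxia and glycolysis genes had a median of 1.10, with HK2 at 3.56 and SLC2A3 at 3.50. Epidermal differentiation (-2.78), Notch (-1.92, with HES2 at -5.06 and MAML2 at -3.79), cholesterol synthesis (-1.03) and histones (-2.71, with HIST1H4H at -4.78) were lower, and DNA replication (1.07), fibroblast markers (1.63, with COL1A1 at 5.13 and LUM at -5.64), ribosomal proteins (0.43) and mitochondrially encoded genes (0.93) higher. With an estimated correlation, the adjusted p was 0.727 for the luminal, mesenchymal, p63 and epidermal lists, 0.724 for hypoxia and glycolysis and 0.862 for the other 9. The chemokine list did not pass, with CXCL1 (-6.43), CCL28 (-4.88) and CXCL16 (-4.13) lower and CXCL12 (5.16) higher in SUM1315.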

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

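All 13 results of this part are gene lists whose shΔNp63 effect differed between the lines past the threshold with the preset correlation, and the explanations weighed below and the test at 5 TPM were chosen after the results were seen. The median differences, SUM1315 minus HCC1806RR, were 1.139 for p63 epithelial targets, 1.215 for basal keratins and markers, 0.896 for the mesenchymal list, 0.957 for NF-κB targets, 1.002 for interferon response, 0.952 for MHC class I, 0.898 for Wnt, 1.596 for Notch, 1.654 for fibroblast markers and 0.75 for ribosomal proteins. They were -0.367 for mitosis, -0.614 for DNA replication and -1.076 for mitochondrially encoded genes. With 1 library left out the mitosis difference ranged from -0.99 to 0.255 and the DNA replication difference from -1.037 to -0.062. With an estimated correlation none passed (adjusted p = 0.792 for each). Over genes with a mean of at least 5 TPM in each line, 11 of the 13 passed again with the preset correlation, and none of the 11 with an estimated one. Basal keratins and fibroblast markers had too few such members to test. No group held enough libraries for a test of single libraries.

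The SUM1315 library labelled shΔNp63 replicate 2 stood apart from the other SUM1315 libraries. On the axis from the vector library at 0 to shΔNp63 replicate 1 at 1 it projected at 0.775 (SD 0.104 over 20 parts of the genes). However, the axis and the projection share 1 vector library, and TP63 (160% of vector) and CXCL2 (189%) go the other way. All genes share part of those rises, since their median log2 difference from the vector was 0.357 in this library. Mitochondrially encoded genes took 14.7% of its TPM against 34.8% in the vector library. Since TPM has a fixed total, a lower mitochondrial share raises the values of the other genes. A vector library under a wrong label therefore stays open. A batch signature shared by the replicate 2 libraries stays open too: r was 0.00836 between the lines across genes, but replicate 2 minus replicate 1 moved the same way in HCC1806RR and SUM1315 for DNA replication (-0.847 and -1.308), mitochondrially encoded genes (-0.521 and -1.416) and histones (0.838 and 1.226), while mitosis (-1.374 and 0.388), Notch (1.004 and -0.228), ribosomal proteins (0.756 and -0.227) and the unfolded protein response (-0.372 and 0.685) moved apart. A slower or stressed culture could not be told. The DNA replication list lay at -1.31 against all genes, with 34 of 35 members below, and the unfolded protein response at 0.685. However, mitosis lay higher, at 0.388, and hypoxia and glycolysis genes at -0.214 (SEM 0.175). The growth rate itself was not measured.

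The p63 target and Notch lists had lower medians in the single HCC1806RR shΔNp63 library, with calls at the preset correlation that were lost with an estimated one (adjusted p = 0.729 for both). A high vector replicate 2 does not account for all of it, since the p63 list lay at -0.678 against vector replicate 1 alone, with 25 of 29 members below both vector libraries, and Notch at -0.857 against vector replicate 1 and -1.98 against vector replicate 2, which carries a large part of the Notch shift. A general loss of epithelial transcripts does not account for all of it either, since the luminal median lay above the p63 median by 0.791. The SE of 0.256 is over genes, which are not independent. Against all genes the luminal list lay at 0.218 with vector replicate 1 and -0.248 with vector replicate 2, where the p63 list lay at -0.678 and -0.834. Whether lower TP63 has the same effect in SUM1315 could not be told: in replicate 1 the p63 list lay at -0.0636 against all genes (SEM 0.0671 over 29 members, of which 18 reached 5 TPM), in 1 pair of libraries. The criteria for this outcome and for those of the paragraph above were made stricter after the values were seen.

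Short RNA genes ranked high in the comparisons of shΔNp63 with vector. Genes under 200 nt numbered 8, 9, 19 and 11 among the 50 smallest p-values of the 4 comparisons, at least 6.06 times their share of 2.64% among tested genes with a length. The 5 such genes named in the report had at most 5 estimated reads in any library, so a few reads could account for their rank.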

How the results depend on the processing

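The alternatives fixed in advance are joined here by fits chosen after the data were seen: replicate 1 libraries alone, protein-coding genes alone, genes of at least 200 nt, genes of at least 5 TPM in each line (lists of the difference alone) and 1 line at a time. Of 174 summary values 144 stayed the same and 30 moved; of 821 list medians 594 stayed, 216 weakened and 11 reversed; and of 1598 gene values 1502 stayed, 79 weakened, 15 strengthened and 2 reversed. Except where stated, the cause was not tested. The numbers that stayed are no measure of robustness, since some settings cannot move a value. A filter, the variance trend or a library of the other line does not enter a gene's log2 difference within a line. TP63 in HCC1806RR, for example, was at -3.27 without a filter, without a trend and without either SUM1315 shΔNp63 library. Among the summary values, a count with no gene past the threshold in either fit also adds to those that stayed.

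Without a filter 393 genes passed in HCC1806RR, 406 in SUM1315 and 676 in the difference, of which 387, 402 and 666 had a mean TPM under 1. Of the 393, 406 and 676 genes, 342, 360 and 589 were above 0 in 1 library alone. In HCC1806RR 4 genes passed at a mean TPM of at least 5 and 8 among protein-coding genes. Genes of at least 200 nt and libraries of that line alone gave 0 and 0. Between vector groups 616 genes were lower and 855 higher without a filter, and 1257 were higher with median-of-ratios scaling and 1595 with quantile normalization. Leaving out 1 library gave 0 to 797 genes higher and 0 to 2369 lower. The correlation of effects was 0.034 among replicate 1 libraries. With replicate number as a block, or with cell line and number paired, 0 and 0 genes passed over both lines.

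With an estimated correlation 0 lists passed over both lines, 0 in HCC1806RR, 0 in SUM1315, 0 in the difference and 0 between vector groups. By fry these were 0, 0, 0, 0 and 5. Over both lines 8 lists passed without a filter, and 8 to 15 when 1 library was left out, with 1 of 15 calls kept each time; in HCC1806RR 17 passed at a mean TPM of at least 5.

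Leaving out 1 library, medians over both lines ranged from -0.561 to 0.222 for basal keratins, 0.007 to 0.96 for the mesenchymal list, -1.538 to 0.03 for Notch, -0.57 to 0.44 for interferon response, 0.115 to 0.654 for mitosis, -0.472 to 0.192 for DNA replication, -0.549 to 0.297 for ribosomal proteins and -0.868 to 0.238 for mitochondrially encoded genes. They ranged from 0.082 to 0.6 for the unfolded protein response, 0.008 to 1.074 for histones and 0.032 to 0.43 for TGF-β and YAP targets. For chemokines the range was -0.492 to 0.011, and for proteases and inhibitors 0.02 to 0.215. Without HCC1806RR shΔNp63 replicate 1 the mitosis median was 0.217 while the test pointed down. Among replicate 1 libraries mitosis was -0.049 and ribosomal proteins 0.077. The HCC1806RR DNA replication median ranged from -0.203 to 0.572, CXCL1 over both lines from -1.916 to 0.142 and TP63 in SUM1315 from -1.156 to 0.66.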

Other observations

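Both hypotheses in this part were written before their own tests were run, but they arose from genes already seen in the comparisons. Beyond the genes of the report, NTF3, a neurotrophin, stood at 5.52 TPM in HCC1806RR shΔNp63 against 1.9 and 1.98 TPM in vector, and at 4.24 and 7.47 TPM in SUM1315 shΔNp63 against 0.774 TPM. The heparan sulfatase SULF2 stood at 48.5 TPM against 22.4 and 23.7 TPM, and at 42.2 and 121 TPM against 18 TPM. S100P, a calcium-binding protein, stood at 3.72 TPM against 9.24 and 9.01 TPM, and at 4.3 and 0.691 TPM against 19.7 TPM. DEFB1, a defensin, stood at 1.35 TPM against 15 and 11.4 TPM in HCC1806RR. None of these passed the threshold.

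SAA1, SAA2 and S100A9 raised the question whether other secreted antimicrobial and acute-phase genes were lower in both lines. A list of 24 other genes was written, of which 13 were tested. In HCC1806RR its median lay at -1.34 against all genes (SEM 0.267, 12 of 13 below 0), and in SUM1315 at -0.178 (SEM 0.258, 6 of 13 below 0). By limma's camera the p over both lines was 1.62e-08 with the preset correlation and 0.0751 with an estimated correlation of 0.332. The criteria written in advance were met, but the SUM1315 median lies within its SEM, a requirement added after the values were seen, so the data cannot tell whether the lines share the pattern.

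A shared response to the shRNA would give more genes separated by at least 1 on the log2 scale in every pair of both lines than other assignments of the labels. The real assignment gave 16 such genes and 5 of the other 8 gave 18 to 75, which met the criterion written in advance against a shared response. This outcome was changed to open after the values were seen, for 3 reasons. The highest counts came from assignments that take the library labelled SUM1315 shΔNp63 replicate 2 as the lone vector, the highest of the others with neither replicate 2 library as the lone one was 18, close to 16, and the real assignment needs a library with TP63 above the vector to respond. After the results were seen, the libraries were also split into 3 and 3 in other ways with the cell line as a covariate. The 9 splits that could be fitted are too few for a share under 0.05, with 0 genes past the threshold for the real split and 0 for the highest other.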
